A study of Mus musculus with 8 samples.

How the data were processed

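The samples were early erythroid progenitors taken from E14.5 fetal liver of C57BL/6 mice. Per the labels, lineage-positive, Sca-1-positive, CD16/32-positive, CD41-positive and CD34-positive cells were removed magnetically, and cells positive for c-kit and in the lowest 10% for CD71 were then sorted. The cells received a control virus or a virus carrying 1 of 2 short hairpin RNAs (shRNA1 and shRNA2) against an RNA-binding protein, and were cultured for 3 days. Total RNA of 8 samples was labelled with Cy3 and hybridised to 1-colour arrays, with 2 arrays in each of 4 groups: control virus without DEX, control virus with DEX, shRNA1 with DEX and shRNA2 with DEX. DEX belongs to the glucocorticoids, as the title of the series gives it. The labels call the protein only an RNA-binding protein; that it is Zfp36l2 comes from knowledge of the published study of this design. The labels do not say whether the replicates of a group were separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical.

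Per the file headers, the authors scanned and quantified the arrays with Agilent Feature Extraction 10.1.1.1; the submitters' processing notes name Agilent Feature Extraction and limma without versions. The deposited intensity of a spot (the processed signal) is on a linear scale. Per the file headers, spatial and multiplicative detrending and surrogate values for spots at background were switched on, and a further background correction was switched off. The authors also deposited a table of log2 values, whose steps are not given in the sources used here. Its columns had a Spearman correlation of 1 with the median signal of their own arrays over all spots, controls included, and medians between 6.65 and 6.66, which is what quantile normalization of the log2 median signal gives; it was not centred per gene, and it served only as an alternative. Probe positions are those of the file (mouse build mm9). No annotation of that build was used, so whether a probe lies in an exon or an untranslated region is not stated.

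Each array held 44397 spots, of which 1377 were controls and were left out. Spots carrying an outlier mark of the scanner software were left out, spots of 1 probe were averaged, and 441 of 39429 probes lacking a usable spot on some array were not used. The signal was taken as log2 minus the 75th percentile of its array. Names of 26581 probes came from a match of the probe's accession to the reference table of gene names, and 12848 probes kept the name in the file. A probe was tested if it was well above background on both arrays of at least 1 group, and a gene was represented by its probe with the highest mean over all arrays; 3900 of the 19128 genes tested had several probes. Near-identical genes, such as the globin copies, may share signal, so their separate values are uncertain.

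Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 8 arrays and 4 groups in 1 fit, at a Benjamini-Hochberg adjusted p below 0.05. Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, and again with a correlation estimated from the data. P-values were adjusted over the 22 lists within a comparison. With an estimated correlation camera also tests on the residual degrees of freedom alone, 4, or 3 with the slide as a block (below). Few lists could then pass, whatever their correlation. A list's value is the median log2 fold change of its members minus the median of all genes tested, because the scaling moved the latter by more than 0.1. That median was -0.08 for DEX, 0.18 for shRNA1 and 0.01 for shRNA2; with the array's median as the scale it was 0.02, -0.22 and -0.23, and with quantile normalization -0.02, -0.00 and -0.05. Tables were handled with data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9.

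The 22 lists were glucocorticoid receptor targets, the ZFP36 family, published ZFP36 family mRNA targets, globins and haem synthesis, red cell membrane and late erythroid genes, erythroid regulators, early progenitor genes, mast cell and basophil markers, neutrophil and granulocyte precursor markers, monocyte and macrophage markers, megakaryocyte and platelet markers, hepatocyte markers, lymphoid markers, S phase genes, G2 and M phase genes, cell cycle inhibitors, interferon response, p53 targets, immediate early genes, ATF4 and unfolded protein response, hypoxia and glycolysis genes, and cholesterol synthesis. Some genes stand in more than 1 list: 9 of the 24 measured published targets and 8 of the 18 measured immediate early genes were shared with another list, and 1 granulocyte marker (Lcn2) was also a glucocorticoid receptor target.

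The genes named in the text follow a rule: the 8 largest rises and the 8 largest falls among genes with a symbol that passed the threshold with no overlap between the arrays of the 2 groups, 5 per direction for the difference between the shRNAs, or the 4 with the smallest p where none passed; per list up to 4 members that passed, otherwise the 2 with the smallest p; and always Zfp36, Zfp36l1 and Zfp36l2. A few genes that the rule selects are not reported here by name, although the counts and list values include them. Groups, tests, lists, this rule and the alternatives first tried were fixed before the data were examined. Because no gene passed without a block, the same rule was also applied to the fit with the slide as a block, a choice made after the result was seen. Where every array of a group read a probe as not well above background, the fold is a lower bound: the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

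Replicate 1 of every group lay on 1 slide and replicate 2 on another, as the deposited files show, so the slide is a batch that holds each group once, and the position of an array on its slide coincided with its group. The first principal component, with 65.9% of the variance, separated the slides. On it the first-slide arrays of shRNA1 (-120) and shRNA2 (-102), the dimmest arrays, also lay apart from the first-slide controls (-7.4 without DEX and -29.2 with DEX). Deviations of same-slide arrays from their group means correlated at 0.431 to 0.859. With 2 replicates such a correlation does not by itself pair the samples; the shared slide does, and values with the slide as a block and within each slide are therefore given. Alternatives were quantile and median scaling, normexp background correction with an offset of 50, no filter on dim probes, the mean of a gene's probes, the authors' table, the slide as a block, and each array left out in turn, where the lone array of a group was assumed to vary like the other groups. A repaired normexp, in which aberrant local backgrounds were replaced, was added after the normexp result was seen.

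Arrays differed in brightness. The 75th percentile of the signal ran from 476 to 2061 intensity units, a ratio of 4.33, and was lower on every array of the first slide (1003, 966, 476 and 522) than on the second (1923, 2061, 1439 and 1665, in the order of the groups above). Between 59.5% and 62.9% of probes were well above background, and 0 spots were saturated. The number of arrays, 2 per group, limits the precision.

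The fits were tested on simulated data made for the DEX comparison of 19128 genes. Without the block, 0 of 67 genes changed by 1 log2 unit, 0 of 67 changed by 2 and 32 of 66 changed by 4 were recovered; with the block 1, 43 and 66 were, and 8 unchanged genes passed as well. A list of 25 genes shifted by 0.6 passed in both fits, and 0 of 20 unshifted lists did. The noise of the simulated genes was independent and the lists were drawn at random. These values therefore do not show how often a list of correlated genes passes falsely. In the data the estimated correlation without a block was 0.82 for granulocyte markers and 0.93 for G2 and M phase genes, among the highest of the 22 lists. It was 0.558 for globins and haem synthesis, 0.294 for red cell membrane genes and 0.067 for receptor targets. With the slide as a block these 3 were 0.097, -0.009 and -0.012, while granulocyte markers had 0.961 and G2 and M phase genes 0.929.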

Results

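Expression was measured in 8 samples of cultured mouse fetal liver erythroid progenitors on 1-colour arrays, with 19128 genes tested. The 4 groups of 2 arrays each were control virus without DEX, control virus with DEX, shRNA1 with DEX and shRNA2 with DEX. The comparisons asked which genes respond to the glucocorticoid in these cells, which respond to loss of the RNA-binding protein under DEX, and how the 2 sets of changes relate. Values are normalized log2 signals, and changes are log2 differences with the standard error (SE) of the fit.

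Zfp36l2, an RNA-binding protein that promotes the decay of AU-rich mRNAs, was higher with DEX and lower with each shRNA (probe on chromosome 17, 84583415 to 84583474, build mm9). Its normalized level was 3.67 ± 0.25 (SD, n = 2) without DEX and 5.49 ± 0.09 with DEX in control cells, and 4.0 ± 0.12 with shRNA1 and 3.91 ± 0.30 with shRNA2. The change with DEX was 1.82 (SE 0.31), a fold of 3.53, and was 2.06 on the first slide and 1.57 on the second. With shRNA1 the change was -1.49 (slides -1.47 and -1.50). With shRNA2 it was -1.58 (-1.43 and -1.73), and both shRNA groups lay near the level without DEX. The related genes moved less: Zfp36l1 differed by -0.58 with DEX (SE 0.30), 0.52 with shRNA1 and 0.13 with shRNA2. Zfp36, well above background on 1 of 2 arrays in each group with DEX, differed by -0.71, 0.84 and 0.31 (SE 1.34). In limma without a block, Zfp36l2 passed when adjusted over the list alone (3 genes: adjusted p = 0.00292 for DEX, 0.0084 for shRNA1 and 0.00613 for shRNA2). Over all genes it did not pass (adjusted p = 0.373, 0.923 and 1; with the slide as a block 0.0721, 0.229 and 0.751). Leaving out 1 array ended the call over the list alone for shRNA1 without either control array with DEX or without shRNA1 replicate 2 (limma adjusted p up to 0.0734). The call for shRNA2 ended without control with DEX replicate 1 (limma adjusted p = 0.0575). That for DEX held in 8 of 8 cases, and with the block all 3 did. The call for shRNA1 also ended with the planned normexp. As a group of 3, the ZFP36 family passed in no comparison (adjusted p = 0.335, 0.444 and 0.0905), and its medians (-0.51, 0.34 and 0.12) had the opposite sign of its tests and of its means (0.18, -0.04 and -0.38).

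**Figure D1:**
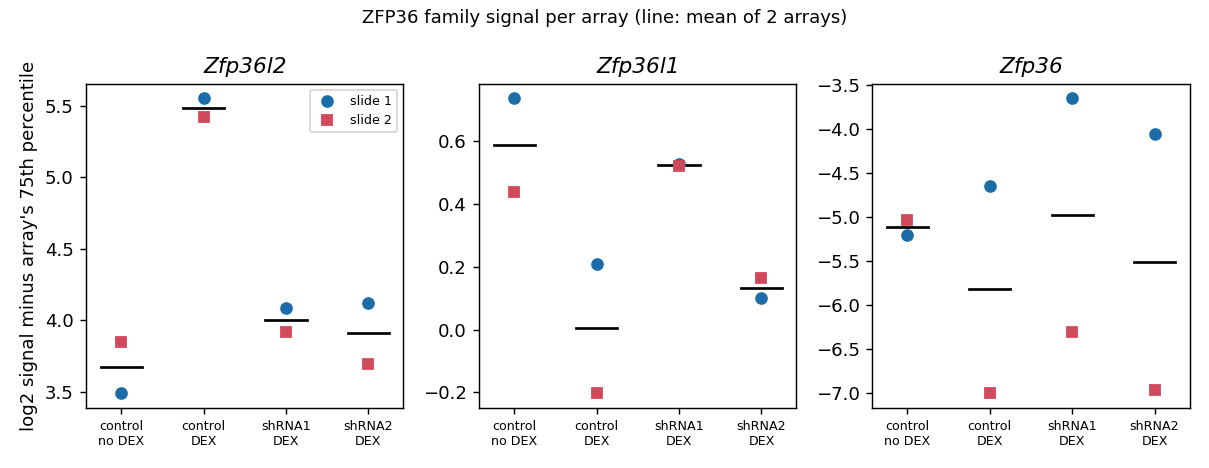
Normalized log2 signal of Zfp36l2, Zfp36l1 and Zfp36 on each of the 8 arrays, by group; circles are slide 1, squares slide 2 and the line is the group mean. Zfp36l2 averages 5.49 with DEX in control cells and between 3.67 and 4.0 in the other groups.

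With DEX, the genes with the strongest statistical evidence were Arhgef3, a guanine nucleotide exchange factor, at 3.99 (SE 0.34), Gna14, a G protein alpha subunit, at 3.03 (SE 0.31), Mgll, which hydrolyses monoglycerides, at -3.39 (SE 0.29) and Nacad at -3.38 (SE 0.32). The metallothionein gene Mt2, which binds metals, was higher by 4.28 (SE 0.47). Limma without a block called 0 genes (smallest adjusted p = 0.154), against 594 at an unadjusted p under 0.05 where 956 are expected by chance. On both slides 714 genes differed by at least 2-fold the same way, 321 higher and 393 lower, and 58 did so in opposite ways.

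With the slide as a block, 44 genes passed, 27 higher and 17 lower, and 1827 had an unadjusted p under 0.05. Among the largest rises in that fit were Rasd1, a Ras-related gene first described as induced by dexamethasone, at 4.35 (slides 4.27 and 4.44), Mst1r, a receptor tyrosine kinase, at 4.1 (4.32 and 3.89), Mt2 (4.0 and 4.56) and Arhgef3 (4.28 and 3.71). Several genes were not well above background without DEX, so their rises are bounds. Trnp1 was at least 210.04-fold higher, Fetub, a plasma protease inhibitor, at least 36.8-fold, Adamts14, a procollagen-processing protease, at least 27.3-fold, and Tnr, the matrix protein tenascin-R, at least 11.1-fold. The largest falls were those of Prss50 (-3.74), Artn, a ligand of the GDNF family (-3.70), Mgll (slides -3.52 and -3.25) and Nacad (-3.56 and -3.20). Others were the phosphatase gene Ptpn14 (-3.03), the ascorbate transporter Slc23a1 (-2.86) and the vesicular glutamate transporter Slc17a7, at least 4.13-fold lower. Other probes disagreed for Adamts14 (1.07), Trnp1 (5.66) and Mgll (-3.70 to -0.07), and Rasd1 and Mst1r were well above background on 1 of 2 arrays without DEX. The blocked count fell to 0 without control without DEX replicate 2, without either control array with DEX, without either shRNA1 array or without shRNA2 replicate 2. It was 1 (0 of the 44) without control without DEX replicate 1 and 104, with all 44, without shRNA2 replicate 1. It was 16 with quantile scaling, 112 with median scaling, 72 in the authors' values, and 0 with no filter on dim probes. Of the calls 61.4% were higher as given, 68.8% with quantile scaling, 66.1% with median scaling and 51.3% of 236 with the repaired normexp.

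**Figure D2:**
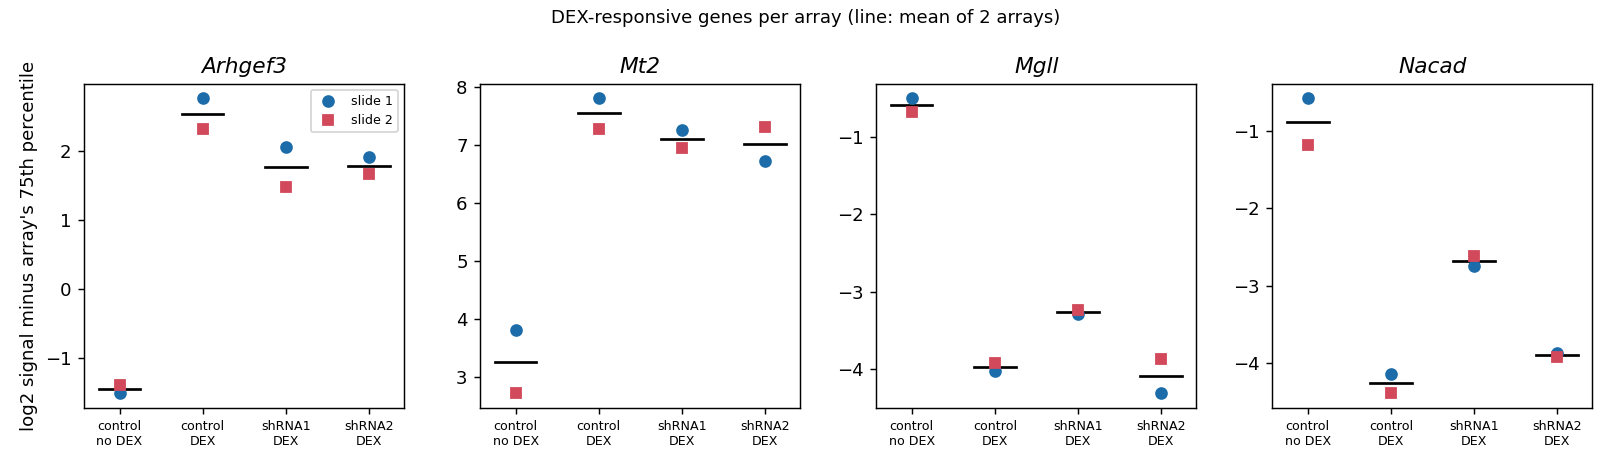
Normalized log2 signal of Arhgef3, Mt2, Mgll and Nacad on each of the 8 arrays, by group; circles are slide 1, squares slide 2 and the line is the group mean. With DEX in control cells Arhgef3 differs by 3.99 and Mt2 by 4.28, and Mgll by -3.39 and Nacad by -3.38.

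Known glucocorticoid receptor targets rose as a group with DEX. Of 29 measured members 23 were higher, with a median 0.68 above that of all genes (0.84 on the first slide and 0.46 on the second). Adjusted over the list alone, 4 passed: Mt2, Fkbp5, a co-chaperone of the receptor, at 2.18 (SE 0.54), Hif3a at 1.52 (SE 0.34) and Cdkn1c, a cyclin-dependent kinase inhibitor, at 2.16 (SE 0.53), against 0 over all genes. With the slide as a block 12 passed over the list alone, among them Per1 of the circadian clock at 1.26 and Tsc22d3, an anti-inflammatory target, at 1.23. The group's call (camera adjusted p = 1.63e-12) was kept with each of the 8 arrays left out (0.53 to 0.84), and the adjusted p = 0.164 with an estimated correlation. Mt2 alone of the 4 kept its call over the list with each array left out; for Fkbp5, Hif3a and Cdkn1c it was lost in all 8 cases (adjusted p up to 0.304). These 3 also lost it at median scaling, with both forms of normexp and with no filter on dim probes, and Cdkn1c in the authors' values. The blocked count of 12 fell to as few as 2, without control with DEX replicate 2.

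Genes of red cell maturation fell as groups with DEX. Globins and haem synthesis genes lay 0.51 below all genes in the median (a value of -0.51; slides -0.53 and -0.50), with 20 of 23 measured members lower. Red cell membrane and late erythroid genes lay at -0.39 (-0.54 and -0.45), with 29 of 36 lower, and erythroid regulators at -0.37 (-0.38 and -0.30), with 15 of 20 lower. Adjusted over the list alone and without a block, Dmtn, a protein of the membrane skeleton, fell by 2.35 (SE 0.33) and Acp5, an acid phosphatase that is not specific to red cells, rose by 3.06 (SE 0.32). With the slide as a block, 9 haem and globin genes passed as lower over the list alone, among them Ahsp, a chaperone of alpha globin, at -1.28, Uros at -1.35 and Alas2, the first enzyme of erythroid haem synthesis, at -1.62. In the same fit 13 membrane genes were lower and 1 (Acp5) higher, with Slc4a1, the anion exchanger of red cells, at -2.04 and Fn3k at -2.95. In it 4 regulators were lower, among them Bcl2l1, which protects maturing red cells from death, at -1.14 and Sox6 at -1.44. Camera called the 3 groups (adjusted p = 7.67e-06, 5.43e-05 and 0.00359), and with an estimated correlation the adjusted p = 0.757 for each. Without control with DEX replicate 2 all 3 calls were lost (-0.37, -0.31 and -0.28; adjusted p = 0.063, 0.0566 and 0.0646), and without control without DEX replicate 1 those of the membrane genes (-0.19, adjusted p = 0.122) and the regulators (-0.20, 0.142). The globin value ran from -0.82 without control with DEX replicate 1 to -0.30 without control without DEX replicate 1, and membrane genes lay at -0.59 without control without DEX replicate 2. Dmtn lost its call without either control array with DEX (adjusted p up to 0.0859), at median scaling and with the planned normexp. The blocked counts of 9, 13 and 4 fell to 0, 2 and 0 without control with DEX replicate 2. With 1 array left out the globin count was 0 in 3 of 8 cases and the regulator count in 6. With the planned normexp correction, which failed on spots with aberrant local background, the 3 medians turned to 0.44, 0.33 and 0.67, and the regulators were called as higher (adjusted p = 0.0253; 0.184 and 0.166 for the others).

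Interferon response genes and the markers of monocytes and of megakaryocytes were also lower as groups with DEX. Interferon genes fell as a group by 0.79 in the median (a value of -0.79; slides -0.60 and -1.32), with 19 of 25 members lower, and 6 passed over the list alone with the slide as a block, including the antiviral genes Ifit1 (-3.78), Rsad2 (-2.95), Isg15 (-2.40) and Usp18 (-1.72). Monocyte and macrophage markers lay at -0.97 (slides -0.23 and -1.85), among them Csf1r at -1.05 and Marco at -1.67, and megakaryocyte and platelet markers at -0.95 (-0.60 and -1.18), among them Ppbp at -2.85 and Pf4 at -1.86. The p53 targets rose as a group by 0.29 (slides 0.30 and 0.35), with Perp at 2.88 and Pmaip1 at 1.60 higher and Gadd45a at -1.78 and Sesn2 at -0.94 lower in the blocked fit over the list alone. Camera called these 4 groups (adjusted p = 0.00626, 0.00694, 0.008 and 0.0047), and the adjusted p = 0.833 with an estimated correlation, or 0.823 for the p53 targets. The block ended the calls of the monocyte (adjusted p = 0.101), megakaryocyte (0.0673) and p53 groups (0.0607). So did leaving out control without DEX replicate 2 for all 4 (interferon -0.58 at 0.0531, monocyte -0.14 at 0.613, megakaryocyte -0.58 at 0.375, p53 0.29 at 0.297). Without control with DEX replicate 2 the interferon (-0.51, 0.206), monocyte (-1.13, 0.063) and megakaryocyte calls (-0.90, 0.0646) were lost, and without control with DEX replicate 1 the monocyte (-0.98, 0.266) and p53 calls (0.16, 0.438), with interferon at -1.28. Without control without DEX replicate 1 the monocyte, interferon and p53 values were -1.65, -1.21 and 0.44. The megakaryocyte call was also lost with the planned normexp (-0.39, 0.488). The interferon value was -0.50 in the authors' values and -0.40 with the repaired normexp, and the monocyte value -0.40 with no filter on dim probes. Without either control array with DEX the blocked counts of interferon and p53 members over the list alone fell to 0.

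With shRNA1, genes of red cell maturation rose as groups. Of 23 globin and haem genes 23 were higher, with a median 0.70 above all genes (0.79 and 0.66 on the slides). Red cell membrane genes lay at 0.42 (0.33 and 0.39), with 31 of 36 higher, and erythroid regulators at 0.21 (0.20 and 0.28), with 17 of 20 higher. Members are counted here against 0, and of all genes 61.2% were higher with shRNA1 on the first slide and 61.5% on the second. With the slide as a block and adjusted over the list alone, 16 globin and haem genes passed, among them Slc25a37, the mitochondrial iron importer, at 1.57, Alas2 at 1.49, Uros at 1.46 and Ahsp at 0.97. So did 10 membrane genes, with Slc4a1 at 1.87 and Dmtn at 1.57, and 4 regulators, with E2f2 at 0.98, Foxo3 at 0.95, Klf3 at 0.85 and Bcl2l1 at 0.81; without the block 0 passed. Camera called the 3 groups (adjusted p = 3.45e-07, 0.000113 and 0.044; adjusted p = 0.918 with an estimated correlation for each). The first 2 calls were kept with each array left out, at 0.37 without shRNA1 replicate 1 to 1.11 without shRNA1 replicate 2 for globins and 0.19 without shRNA1 replicate 1 to 0.65 without control with DEX replicate 1 for membrane genes. Without control with DEX replicate 1 the globin value was 1.08, and without replicate 2 the values were 0.43 and 0.24. Membrane genes lay at 0.26 with no filter on dim probes and 0.15 with the planned normexp, with which globins lay at 0.39. The regulators lost theirs without control with DEX replicate 2 (0.23, 0.151), either shRNA1 array (0.27, 0.124 and 0.05, 0.293) or either shRNA2 array (0.21, 0.0673 and 0.18, 0.0701). They also lost it at median scaling (0.21, 0.175), with no filter on dim probes (0.051, 0.114) and with the planned normexp (-0.02, 0.628). The blocked counts of 16, 10 and 4 fell to 0 without either control array with DEX or either shRNA1 array, and that of the regulators in 7 of 8 cases.

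Granulocyte markers were higher with shRNA1 as well, while early progenitor, S phase and hypoxia genes were lower. All 17 neutrophil and granulocyte precursor markers were higher on both slides, with a median 1.37 above all genes (1.52 and 1.24), among them the secretory granule genes Camp at 2.81 (SE 1.11) and Ngp at 2.62 (SE 1.11). Early progenitor genes fell as a group to -0.45 (-0.30 and -0.45), with Kit, the receptor of stem cell factor, at -1.20 and the surface protein gene Cd48 at -0.95. S phase genes lay at -0.51 (-0.91 and -0.04) and hypoxia and glycolysis genes at -0.54 (-0.70 and -0.34), with P4ha2 at -0.91 and Pgk1 at -0.77; no member of these 4 lists passed over the list alone. Camera called them (adjusted p = 3.03e-05, 0.00386, 0.0362 and 0.000113), and the adjusted p = 0.918 with an estimated correlation, or 0.951 for S phase. The S phase direction turned without shRNA1 replicate 1 (0.40, adjusted p = 0.00793) and without control with DEX replicate 2 (0.04, 0.648), and it was -1.49 without shRNA1 replicate 2 and -0.92 without control with DEX replicate 1. Its call was lost with quantile (0.183) and median scaling (0.175) and in the authors' values (0.184). With the planned normexp granulocyte markers lay at 0.70 and progenitor genes at -0.18. Calls were also lost for granulocyte markers without shRNA1 replicate 2 (1.14, 0.0927), for progenitor genes without control with DEX replicate 2 (-0.08, 0.121; -0.74 without shRNA1 replicate 2 and -0.73 without control with DEX replicate 1) and for hypoxia genes without control with DEX replicate 1 (-0.32, 0.132).

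With shRNA2, the groups that rose were markers of other blood cells. Granulocyte markers lay 2.38 above all genes in the median with 17 of 17 members higher on both slides, but at 4.06 on the first slide and 0.69 on the second. Camp was at 3.76 (SE 1.11), Elane, the neutrophil elastase, at 2.54 (SE 0.97) and Ngp at 3.23. Monocyte markers lay at 1.43 (2.55 and 0.17), with the lysozyme gene Lyz2 at 2.97, and megakaryocyte markers at 1.04 (2.67 and -0.35), with Gp1ba at 0.71. G2 and M phase genes fell as a group to -0.42 (-0.96 and 0.03), with Mki67 at -0.54 and Ccna2 at -0.79, and hypoxia and glycolysis genes to -0.31 (-0.74 and 0.08). Red cell groups did not pass: globin and haem genes lay at 0.09 (0.16 on each slide), membrane genes at -0.20 (-0.31 and -0.08) and regulators at -0.00 (adjusted p = 0.11, 0.0596 and 0.932). The embryonic globins were the globin genes with the largest differences, Hbb-y at 3.31 (SE 1.99), Hba-x at 2.34 and Hbb-bh1 at 2.22, chosen after their values were seen; none passed over the list alone. Camera called the 5 groups (adjusted p = 3.14e-20, 1.19e-05, 1.19e-05, 0.000334 and 0.00322), and the adjusted p = 0.875 with an estimated correlation for each. Without shRNA2 replicate 1, the granulocyte call was kept at 1.12, the monocyte call was lost (0.03, 0.557), and the megakaryocyte (-0.53, 0.0125), G2 and M phase (0.40, 0.00605) and hypoxia groups (-0.14, 0.962) turned direction in the test. Without shRNA2 replicate 2 the values were 3.46, 2.58, 2.56, -1.32 and -0.61. The G2 and M phase call was also lost without control with DEX replicate 2 (-0.12, 0.612) and the hypoxia call without control with DEX replicate 1 (-0.12, 0.36). Without control with DEX replicate 1 G2 and M phase genes lay at -0.765, and without replicate 2 hypoxia genes at -0.65. With the planned normexp the megakaryocyte call was lost (0.43, 0.272) and granulocyte markers lay at 0.82. Monocyte markers lay at 0.39 with no filter on dim probes and 0.93 with the repaired normexp.

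**Figure D3:**
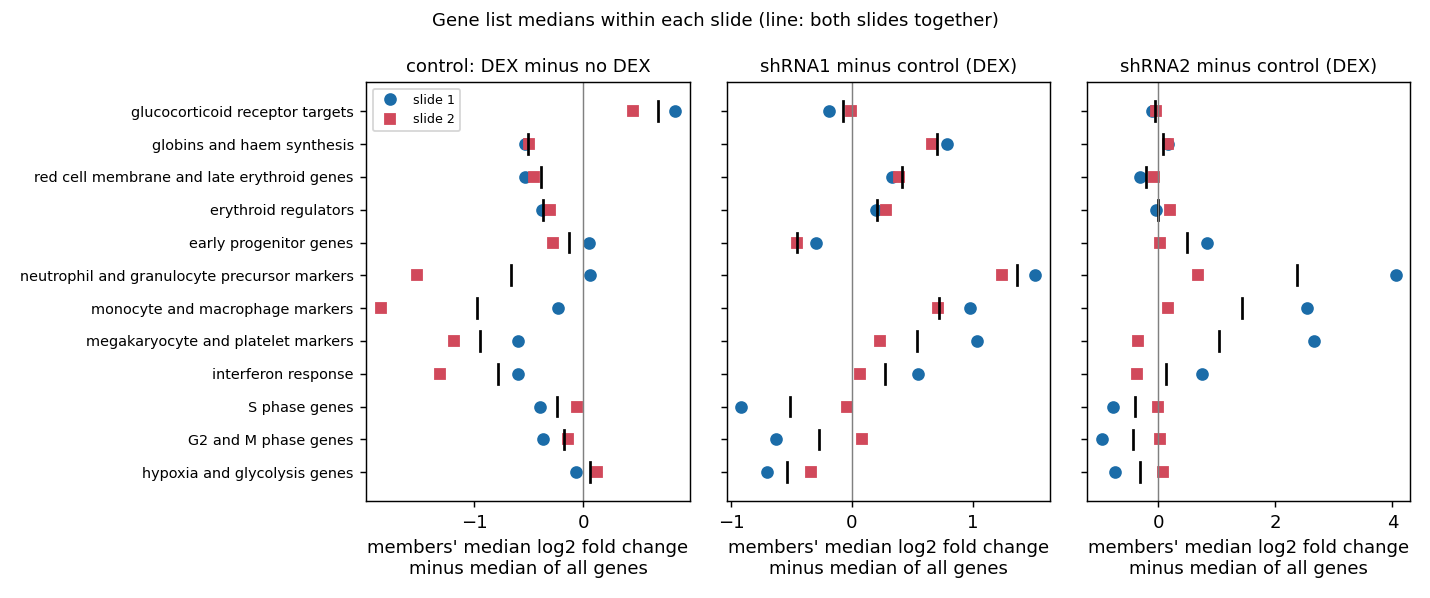
Median log2 difference of 12 gene lists minus the median of all genes, for DEX, shRNA1 and shRNA2, each against its control. Circles are slide 1, squares slide 2 and the vertical line is the value of both slides together. Glucocorticoid receptor targets lie above 0 with DEX on both slides (0.84 and 0.46), and granulocyte markers lie at 4.06 and 0.69 with shRNA2.

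Among single genes, shRNA1 gave its smallest p-values for genes that were not well above background in control cells with DEX. Gal3st3, a sulfotransferase gene, was at least 7.46-fold higher, the chemokine gene Cx3cl1 at least 7.50-fold, the small GTPase gene Rem2 at least 7.27-fold and the olfactory receptor gene Olfr1052 at least 4.24-fold, although another probe of Olfr1052 gave 0.43. With shRNA2 the smallest p-values among genes with a symbol were those of Cox6a2, the muscle form of a cytochrome c oxidase subunit, at 3.19 (SE 0.49), Kctd15, at least 4.22-fold higher, Tifab, at least 2.16-fold higher, and Spink2, a protease inhibitor gene, at -3.65 (SE 0.70). Limma without a block called 0 genes with shRNA1, with shRNA2 and with their mean, against 400, 240 and 263 at an unadjusted p under 0.05 where 956 are expected by chance (smallest adjusted p = 0.37, 0.0751 and 0.17). With the slide as a block it called 0, 1 and 0, against 3407, 1090 and 2263. The 1 gene, named after its value was seen, was the transcript ENSMUST00000055343. Measured at 2.42 with shRNA1, it read as not well above background in control cells with DEX, so this value is not exact. It was at least 5.61-fold higher with shRNA2 (limma adjusted p = 0.0296). It was lost with 1 array left out in 7 of 8 cases or at another scaling, and without shRNA2 replicate 1 the blocked count was 15. Differences of at least 2-fold the same way on both slides numbered 697 with shRNA1 (580 higher, 117 lower) and 195 with shRNA2 (145 and 50). In opposite ways there were 43 and 114. Each shRNA array was dimmer than control with DEX on its slide (75th percentile 476 and 522 against 966, and 1439 and 1665 against 2061). The median of all genes with shRNA1 was 0.18, but -0.22 with median scaling. The excess of rises can therefore not be told apart from brightness and scaling, also where both slides agree.

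The mean of both shRNAs was the comparison with the most arrays. Granulocyte markers lay at 1.80 (slides 2.77 and 0.81), monocyte markers at 1.15 (1.53 and 0.37), megakaryocyte markers at 0.77 (1.79 and -0.05) and globin and haem genes at 0.44 (0.52 and 0.34), with 23 of 23 globin and haem genes higher. Hypoxia and glycolysis genes lay at -0.48 (-0.75 and -0.08), S phase genes at -0.44 (-0.84 and -0.02) and G2 and M phase genes at -0.33 (-0.72 and 0.08). Camera called these 7 lists (adjusted p = 5.24e-13, 0.000553, 0.00601, 3.09e-05, 8.36e-05, 0.0141 and 0.00601; adjusted p = 0.927 with an estimated correlation for each). The calls of both cell cycle lists ended in the authors' values (adjusted p = 0.0764 and 0.0589), without control with DEX replicate 2 (0.07 and 0.03), shRNA1 replicate 1 (0.01 and -0.01) or shRNA2 replicate 1 (0.00 and 0.08), and at median scaling (adjusted p = 0.231 and 0.169), and that of S phase genes also with quantile scaling (0.102). Globins lost theirs without control with DEX replicate 2 (0.16, 0.121; 0.94 without replicate 1), monocyte markers (1.33, 0.147) and hypoxia genes (-0.38, 0.147) without control with DEX replicate 1. So did megakaryocyte markers without shRNA2 replicate 1 (0.04, 0.951), with the block (0.0965), with the planned normexp (0.55, 0.212) and with the repaired one (0.0563). Granulocyte markers ran from 1.18 without shRNA2 replicate 1 to 2.42 without replicate 2 and lay at 0.80 with the planned normexp. Without shRNA2 replicate 1 monocyte markers lay at 0.50, hypoxia genes at -0.27 and globins at 0.27, and without shRNA2 replicate 2 globins lay at 0.68, megakaryocyte markers at 1.43, S phase genes at -0.95 and G2 and M phase genes at -0.80. Without shRNA1 replicate 1 globins lay at 0.245, and without shRNA1 replicate 2 the cell cycle lists at -0.96 and -0.75. Without control with DEX replicate 1 the cell cycle lists lay at -0.88 and -0.73 and megakaryocyte markers at 1.2, and without replicate 2 monocyte markers at 0.63. Monocyte markers lay at 0.45 with no filter on dim probes, 0.61 in the authors' values and 0.67 with the repaired normexp, with which globins lay at 0.26 and hypoxia genes at -0.31.

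The genes that moved alike with both shRNAs, by the largest of their p-values, were Cox6a2 (2.44 with shRNA1 and 3.19 with shRNA2), Zfp36l2 (-1.49 and -1.58), Igfbp6, which binds insulin-like growth factors (1.71 and 1.65), and the zinc finger gene Zfp459 (-1.61 and -1.36). None passed the threshold in both, with or without the block, so 0 genes were called alike by limma. At an unadjusted p under 0.05 with the block, 287 genes were higher with both shRNAs, of 2555 and 539 with each, where independent lists would share 72.0 and unchanged groups with the same control arrays shared 123 in 20 simulations. For lower genes the number was 164 of 852 and 551, against 24.5 and 120. The simulated lists were those of unchanged groups, not matched in length to the lists found, such as the 2555 higher genes with shRNA1. The simulated 123 and 120 therefore do not show how many genes lists of these lengths would share. Across genes, which are not independent replicates, the changes correlated at r = 0.577, with a covariance of 0.173 against 0.0984 simulated for unchanged groups, a difference of 0.0748. Between shRNA1 on 1 slide and shRNA2 on the other, which share no array, r was 0.0791 and 0.307.

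Between the shRNAs, camera called red cell groups as higher with shRNA1 and early progenitor genes as higher with shRNA2, but not with an estimated correlation. For shRNA1 minus shRNA2 the membrane genes lay at 0.58 (adjusted p = 1.88e-09; 0.645 with an estimated correlation), globin and haem genes at 0.53 (4.14e-05; 0.818) and progenitor genes at -0.79 (2.78e-08; 0.645). The membrane call was kept with each array left out (0.42 to 0.60). The globin call was lost without shRNA1 replicate 1 (0.19, 0.154) and shRNA2 replicate 2 (0.29, 0.146), with 0.94 without shRNA2 replicate 1. The progenitor call was lost without shRNA2 replicate 1 (-0.34, 0.146). Among single genes, Slc4a1 was at 1.85, Rhd, which carries the Rh blood group, at 1.45 and Uros at 1.18 for shRNA1 minus shRNA2, while the progenitor genes Kit and Sox4, which did not pass, were at -0.95 and -1.09. With the block and adjusted over the list alone, 17 membrane genes were higher and 1 lower, and 13 globin and haem genes were higher; without it 0 passed. Without shRNA1 replicate 1, shRNA1 replicate 2 or, for the globins, also either control array with DEX or shRNA2 replicate 2, these counts fell to 0. The genes with the smallest p-values were Rem2, Gal3st3, Cx3cl1 and Olfr1052, at least 5.42-fold, 5.56-fold, 5.40-fold and 3.16-fold higher with shRNA1 (another probe of Olfr1052 gave 0.09). Limma called 0 genes without the block (smallest adjusted p = 0.613; 456 at an unadjusted p under 0.05) and 0 with it (0.131; 2104), and 353 genes differed by at least 2-fold the same way on both slides.

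Several genes differed one way with DEX and the other way with the shRNAs. Zfp36l2 did so, as did Epha2, an ephrin receptor (2.42 with DEX, -1.80 with shRNA1 and -0.88 with shRNA2), Cox6a2 (-2.59, then 2.44 and 3.19) and Spink2 (at least 14.4-fold higher with DEX, then -2.20 and -3.65); none passed in both comparisons. Because the control arrays with DEX enter both comparisons with opposite signs, part of this may come from the shared arrays. Genes at least 4-fold changed with DEX on 1 slide were therefore compared with the mean of both shRNAs on the other slide, which shares no array with it, a test chosen after the results were seen. Of genes higher with DEX, 195 of 262 on the first slide were lower with the shRNAs on the second (74.4%, against 43.2% of all genes), and 88 of 153 with the slides exchanged (57.5%, against 41.5%). Of genes lower with DEX, 97 of 148 (65.5%, against 56.8%) and 220 of 229 (96.1%, against 58.5%) were higher. With shRNA2 alone the genes lower with DEX on the first slide did not do so, with 62 of 148 higher (41.9%, against 48.7%). With shRNA1 alone the genes higher with DEX on the second slide were lower in 71 of 153 (46.4%, against 38.8%), with a median of 0.055. The 229 genes lower with DEX on the second slide included markers of other blood cells, such as Camp (-2.98) and Ctss (-3.20). Granulocyte markers had a median signal of 1.25 on control without DEX replicate 2, against -1.59 on replicate 1. How far such differences between single arrays make the 96.1% was not tested. All genes, used for comparison, were not matched for signal. On the first slide the lowest signal well above background was -5.41 with shRNA1 and -5.35 with shRNA2, against -6.22 on control with DEX. On the second slide it was -6.47, -6.50 and -6.47. How far brightness makes the 96.1% was not tested either. With shRNA1 alone that share was 96.5%. Across all genes r was -0.398, where unchanged groups sharing those arrays gave -0.577 in 100 simulations. The covariance was -0.111 against a simulated -0.0983, a difference of -0.0128; for shRNA1 alone the difference was -0.0255 and for shRNA2 -2.67e-05. With DEX on 1 slide and the shRNA mean on the other r was -0.196 and -0.427, and within the slides -0.144 and -0.457. Without 1 array it ran from -0.187 to -0.732 (without control with DEX replicate 1) and -0.720 (without replicate 2).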

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

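All tests of explanations given here were chosen after the results they bear on had been seen; the comparison between the shRNAs itself was planned.

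Tests of the difference between the shRNAs called 7 gene lists, given as the median for shRNA1 minus shRNA2 relative to all genes, and 0 with an estimated correlation; its adjusted p follows that of the preset one. Red cell membrane genes differed by 0.58 (slides 0.68 and 0.57; camera adjusted p = 1.88e-09 and 0.645), with 33 of 36 members higher with shRNA1. Globin and haem genes differed by 0.53 (adjusted p = 4.14e-05 and 0.818) and erythroid regulators by 0.34 (slides 0.48 and 0.13; 0.0154 and 0.818). Early progenitor genes differed by -0.79 (2.78e-08 and 0.645), with 22 of 27 members lower with shRNA1, and the published ZFP36 family mRNA targets by -0.34 (slides -0.25 and -0.28; 0.00541 and 0.645). Granulocyte markers differed by -1.01 (7.64e-05 and 0.818) and megakaryocyte markers by -0.51 (0.00541 and 0.818), but the slides had opposite signs, -2.36 and 0.49 for the first and -1.60 and 0.45 for the second. With the slide as a block 9 lists were called, and 0 with an estimated correlation; p53 targets (0.27, adjusted p = 0.00865; 0.0534 without the block) and immediate early genes (-0.21, 0.0485; 0.134) were added. Membrane genes kept their call with each array left out (0.42 to 0.60). Without shRNA2 replicate 1 the granulocyte (0.47, 0.208) and megakaryocyte differences (0.97, 0.000536) turned, the globin difference was 0.94, and the calls of progenitor genes (-0.34, 0.146), regulators (0.03, 0.38) and published targets (-0.20, 0.351) were lost. The globin call was lost without shRNA1 replicate 1 (0.19, 0.154) and shRNA2 replicate 2 (0.29, 0.146), that of the regulators without either shRNA1 array (0.22, 0.16 and 0.21, 0.18), and those of the published targets (-0.31, 0.0997) and megakaryocyte markers (-0.11, 0.42) without shRNA1 replicate 2. Without shRNA2 replicate 2 granulocyte and megakaryocyte markers lay at -2.14 each and published targets at -0.54, and megakaryocyte markers at -1.02 without shRNA1 replicate 1. With the planned normexp, which failed, the calls of published targets (-0.26, 0.575), granulocyte (-0.07, 0.379) and megakaryocyte markers (0.21, 0.486) were lost.

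Granulocyte markers were higher with both shRNAs, most on the array of shRNA2 replicate 1. That this array alone makes the pattern was argued against by the median of 1.36 with shRNA1 on the other slide (1.24 relative to all genes). Median scaling shifts a list and all genes alike, so a median relative to all genes cannot test it. Scaling was argued against by the lowest median relative to all genes with shRNA2, 1.99, over quantile scaling, the authors' values and the repaired normexp. With the planned normexp, which failed, it was 0.82 (adjusted p = 0.0167). Whether that culture held a larger share of granulocytic cells stays open: the lower quartile of the 17 members there was 3.86, which restates the rise and does not decide it. Lineage-positive, CD16/32-positive and CD41-positive cells had been removed before the culture, so such cells would have had to escape the sort or arise afterwards. The rise on that array was not particular to granulocyte markers. Relative to all genes, megakaryocyte markers lay there at 2.67, monocyte markers at 2.55, mast cell markers at 0.89 and early progenitor genes at 0.84, and G2 and M phase genes at -0.96. A change of expression within the erythroid cells stays open too and was not tested. Granulocyte markers also varied between control arrays without DEX, with median signals of -1.59 on replicate 1 and 1.25 on replicate 2. On the second slide the signal was -0.34 on control with DEX, 0.96 with shRNA1 and 0.53 with shRNA2. Both shRNA arrays thus lay below the control without DEX there, so that slide does not settle whether the knockdown caused the rise.

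Globin and haem genes were lower with DEX and higher with shRNA1. Camera called neither change with an estimated correlation (adjusted p = 0.757 and 0.918). Scaling was argued against by the median relative to all genes nearest to 0, -0.49, over quantile scaling, the authors' values and the repaired normexp. Median scaling cannot change such a value. With the planned normexp, which failed, the median with DEX was 0.44. Noise of the control arrays with DEX, which enter both comparisons with opposite signs, stays open. DEX on 1 slide and shRNA1 on the other, which share no array, had opposite signs, the median nearest to 0 being -0.53 (relative to all genes -0.50). There are only 2 such control arrays, however, and without replicate 2 of them the DEX call ended (-0.37, adjusted p = 0.063), while that with shRNA1 was kept without either (1.08 and 0.43). A shift in the share of cell types stays open for shRNA1. The granulocyte list was higher as well, at a median of 1.55 (1.37 relative to all genes). That argues only against a trade of granulocytic for erythroid cells. Early progenitor genes were lower (-0.45 relative to all genes), and a smaller share of progenitors could raise both lists, so the joint rise cannot decide it. An effect of the knocked-down protein on these genes was not tested and stays open. Both shRNAs lowered Zfp36l2 (-1.49 and -1.58). The globin list lay at 0.09 with shRNA2 and did not pass, while with the mean of both shRNAs it was called (0.44, with 23 of 23 members higher), though not with an estimated correlation (adjusted p = 0.927) or without control with DEX replicate 2 (0.16, 0.121).

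Single genes passed almost only with the slide as a block. Different signal distributions of the arrays were argued against as the only cause. After quantile normalization, which makes them equal, the residual SD without the block was still 1.76 times that with it. Effects of brightness that differ between probes would remain after it and stay open. Separate cultures or cell preparations for the slides could give such a slide effect too, with same-slide deviations correlating at 0.431 or more. Slide and preparation cannot be told apart, since each slide held 1 array of each group.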

How the results depend on the processing

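The estimated correlation was planned with the list tests. The other alternatives were planned too, except the repaired normexp and those run within the fit with the slide as a replicate block. These exceptions were chosen after seeing the data. Planned normexp failed: 0 to 31 spots per array had a local background over 10 times the median, up to 771626 units, and the fitted background mean fell to -2594. This was found after its result was seen, and the repair replaces such backgrounds. Values within a slide have no test. Genes not well above background give only bounds, and with 2 arrays per group small changes were not detectable. Of the other results, 1346 of 1760 for gene lists kept direction and side of the threshold, 60 were no longer called and 132 became called. A further 17 that had been called turned direction. Another 205 that were not called turned direction, 27 of them called in the alternative. Of 3792 for single genes 3605 kept both. Turned directions are counted as reversed only for lists that had been called, a choice made after the first output. Except where a cause is given, the cause was not tested.

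Without a block limma called 0 genes in every comparison, with each array left out too. With the replicate block it called 44 with DEX and 1 with shRNA2. In that fit the DEX count was 16 with quantile scaling, 112 with median scaling, 0 with normexp (314 at an unadjusted p under 0.05), 0 with no filter (1779), 72 in the authors' values, 236 with the repaired normexp and 0 to 104 with 1 array left out. The shRNA2 count was 0 with quantile scaling, median scaling, normexp, no filter, the authors' values and the repaired normexp (1154, 864, 5410, 1200, 1126 and 5335 at an unadjusted p under 0.05), and 0 to 15 with 1 array left out. With the repaired normexp shRNA1 gave 1 and the difference 3, and the mean of both gave 0 to 1 with 1 array left out.

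With normexp the correlation of DEX and shRNA mean was -0.962 (with 1 array left out -0.732 to -0.187). The globin, membrane and regulator medians with DEX were 0.44, 0.33 and 0.67, and the globin median with the shRNA mean -0.41, all reversed; of these the regulators were called as higher (adjusted p = 0.0253). With normexp granulocyte markers lay at 0.70 with shRNA1, 0.82 with shRNA2 and 0.80 with the mean. With shRNA1, globins lay at 0.39, membrane genes at 0.15, progenitor genes at -0.18 and S phase genes at -0.785. With shRNA2, G2 and M phase genes lay at -1.77 and hypoxia genes at -1.69 (-1.03 and -0.98 with the mean, and S phase genes -1.10). With DEX, interferon genes lay at -1.44 and p53 targets at 0.77, and for the difference globins, membrane genes and regulators lay at 1.96, 1.69 and 1.64. Lists called were 13 with shRNA2 and 11 with the mean, and with the block 13 with shRNA2. With no filter shRNA2 gave 8; with the repaired normexp it gave 8 and the difference 11. With quantile scaling and the block the mean gave 10. With an estimated correlation 0 lists were called in each comparison with and without the block. That form of the test has few degrees of freedom, so the loss of calls does not by itself measure correlation. With DEX and the block, receptor targets had an estimated correlation of -0.012, below the preset 0.01. Their camera adjusted p still went from 2.69e-11 to 0.0884.

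With 1 array left out, lists called ran from 5 to 13 with DEX, 4 to 10 with shRNA1, 6 to 9 with shRNA2, 5 to 7 with the mean and 7 to 12 for the difference; with the block from 6 to 12, 4 to 7, 3 to 10, 4 to 7 and 8 to 14. Zfp36l2 ran from 1.64 to 2.00 with DEX, -1.57 to -1.40 with shRNA1, -1.79 to -1.37 with shRNA2 and -1.64 to -1.43 with the mean. With the planned normexp these were 2.51, -1.55, -2.64 and -2.09, and with median scaling 1.91, -1.88, -1.83 and -1.85. Lists that turned ran from -1.49 to 0.40 (S phase, shRNA1), -0.96 to 0.072 (S phase, mean), -0.80 to 0.079 (G2 and M phase, mean), -0.53 to 2.56 (megakaryocyte, shRNA2), -1.32 to 0.40 (G2 and M phase, shRNA2), -0.65 to -0.12 (hypoxia, shRNA2, turned in its test), -2.14 to 0.47 (granulocyte, difference) and -2.14 to 0.97 (megakaryocyte, difference).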

Other observations

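No test of an explanation is given here; the genes of each list were singled out by the named-gene rule or because they passed over their list.

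With DEX, single members of lists that did not pass as groups without a block were higher. Il1rl1, the IL-33 receptor of mast cells, rose by 3.63 (SE 0.64; slides 4.47 and 2.79) and Hdc, which makes histamine, by 2.85 (SE 0.74; 4.04 and 1.65), while the mast cell proteases Mcpt8 and Cma1 were at -2.95 and -2.10. The mast cell list lay at -0.46 (adjusted p = 0.978). Ahsg, a plasma protein of liver, rose by 4.28 (SE 1.03; 4.76 and 3.80), with the apolipoprotein gene Apoa1 at 4.33 (SE 1.44) and Afp at 0.96. Hepatocyte markers lay at 0.18 (mean 1.16; adjusted p = 0.0532, with the block 0.0346, or 0.534 with an estimated correlation). Kit rose by 1.72 (SE 0.31) and Cd48 by 2.38 (SE 0.38), with the transcription factor genes Spi1 at 1.2 and Hhex at 0.99 also passing with the block. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 3.27 (SE 0.56). These calls are adjusted over the list alone, without a block. With 1 array left out Il1rl1 was kept in 6 of 8 cases, Hdc in 4, Ahsg, Kit and Cd48 in 3 each and Egln3 in 2 (p up to 0.0743, 0.252, 0.316, 0.192, 0.147 and 0.23). Kit, Cd48 and Egln3 also lost theirs at median scaling and Cd48 with the planned normexp. Hdc lost it at quantile scaling and with no filter on dim probes, and Ahsg with both forms of normexp, with no filter and in the authors' values.

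Single members of the ATF4 and cell cycle inhibitor lists passed in opposite directions with DEX and shRNA1 in the fit with the slide as a block, adjusted over the list alone. Without the block their lists passed in neither comparison, and the medians of the S phase and of the G2 and M phase genes were below 0 in both. The comparisons share the control arrays with DEX with opposite signs, which favours opposite directions. With DEX the ATF4 pathway genes Slc7a11 (-1.79), Trib3 (-1.70), Ddit3 (-1.58), Sesn2 (-0.94) and Ppp1r15a (-0.86) were lower, and with shRNA1 Trib3, Ppp1r15a, Ddit3 and Sesn2 were higher (1.25, 1.22, 1.19 and 0.96). The kinase inhibitor gene Cdkn1b and the antiproliferative gene Btg2 were at -0.87 and -0.97 with DEX and 0.92 and 0.93 with shRNA1. Cdkn1a (0.79), Rb1 (0.73), Mdm2 (0.88) and Gadd45a (1.36) also passed with shRNA1, and Cdkn2a (1.78) and the transcription factor genes Maff (2.65) and Jun (-1.34) with DEX. Plk3, a published ZFP36 family target, was at 1.40 with DEX, and Il4 at 1.02 with shRNA2. Without a block 0 of these passed over the list alone, and without either control array with DEX the blocked counts of the ATF4, immediate early, cell cycle, p53 and published target lists, and of mast cell markers with shRNA2, fell to 0. With 1 array left out the count fell to 0 in 6 of 8 cases for published targets with DEX, for mast cell markers (Il4) with shRNA2 and for p53 targets with shRNA1.

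The remaining lists did not pass without a block. With DEX, shRNA1 and shRNA2 the medians were -0.03, -0.12 and 0.28 for published ZFP36 family targets (adjusted p = 0.651, 0.512 and 0.0594). They were -0.12, 0.06 and 0.04 for ATF4 and unfolded protein response (0.0532, 0.841 and 0.66; with the block 0.02 for DEX, or 0.534 with an estimated correlation), 0.03, -0.02 and 0.27 for immediate early genes (0.197, 0.721 and 0.318). They were -0.22, 0.42 and 0.20 for cell cycle inhibitors (0.862, 0.324 and 0.916), and 0.04, 0.48 and 0.06 for lymphoid markers (0.862, 0.444 and 0.456). Those of cholesterol synthesis were -0.14, -0.24 and 0.02 (0.3, 0.841 and 0.66). With DEX, early progenitor genes lay at -0.13 (0.3), granulocyte markers at -0.67 (slides 0.06 and -1.52; 0.114), S phase genes at -0.24 (0.158), G2 and M phase genes at -0.17 (0.114) and hypoxia genes at 0.07 (0.197). With shRNA1, glucocorticoid receptor targets lay at -0.07 (0.324), mast cell markers at 0.03 (0.794), and monocyte markers at 0.72 (0.054). Megakaryocyte markers with shRNA1 lay at 0.54 (0.425), hepatocyte markers at -0.40 (0.56), G2 and M phase genes at -0.27 (0.229), interferon genes at 0.27 (0.841) and p53 targets at 0.03 (0.841). With shRNA2, glucocorticoid receptor targets lay at -0.05 (0.546), progenitor genes at 0.49 (0.0582), mast cell markers at 0.81 (0.318), hepatocyte markers at 0.08 (0.825), S phase genes at -0.40 (0.0582; with the block 0.00409, or 0.745 with an estimated correlation), interferon genes at 0.14 (0.932) and p53 targets at -0.12 (0.0602). Median, mean and test differed in sign for published targets, progenitor genes, lymphoid markers and cell cycle inhibitors with DEX, for receptor targets, published targets, mast cell markers, interferon, immediate early and cholesterol genes with shRNA1, and for receptor targets and hepatocyte markers with shRNA2. The means were not taken relative to all genes, whose median with shRNA1 was 0.18. With shRNA1 the means of receptor targets, published targets and cholesterol genes (0.075, 0.118 and 0.034) lay below that median. Their difference in sign therefore comes from the unlike scales.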
